A study of Arabidopsis thaliana with 84 samples.

How the data were processed

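Transcript levels in Arabidopsis thaliana Col-0 roots were measured on 84 Affymetrix ATH1 arrays, 3 for each of 28 groups. Per the labels' protocols, the plants were 12 days old and received 5 mM KNO3, or 5 mM KCl as the control, for 2 h, or for 3.5 h in 2 groups of whole roots. Per the labels' protocols, cells were freed with wall-digesting enzymes and sorted by fluorescence into lateral root cap (LRC), epidermis and cortex (EpiC), endodermis and pericycle (EndoP), pericycle (Peri) and stele (Stele). Unsorted protoplasts were held on ice instead, and other whole roots were incubated in the protoplast solution without enzymes. Treatment is called continuous where KNO3 was kept in that solution and transitory where it was not. Methionine sulfoximine (MSX, 1 mM), an inhibitor of glutamine synthetase, was given to Peri samples, with 5 mM glutamine in 1 group. Per the labels' protocols, RNA of cells was purified on columns and RNA of whole roots with TRIzol. Sorted cells were labelled by a two-cycle protocol from nanogram amounts of RNA, and roots and protoplasts by a one-cycle protocol from microgram amounts.

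The deposited values are log2 expression signals per probe set, between 0 and 14.46, which the authors computed. The labels name no software, background correction or normalization. The log2 scale was read from the values, which unlog to regular steps over a constant at the low end. The experiment files that accompany the arrays hold scanner settings and no measurement, and were not used here. Each array carries 22810 probe sets, of which the 64 Affymetrix controls were left out of the tests. The platform annotation pairs 13513 probe sets with 1 gene, 503 with several and 8794 with none. A symbol other than the locus identifier is given for 1591 probe sets, covering 1563 symbols. A probe set without a gene there is unnamed here, not without a gene, and no gene was named from a probe set with several. Many well-known nitrogen genes therefore have no probe set that can be named here. No genome coordinates were used.

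One-cycle and two-cycle arrays were analysed apart, so no comparison crosses the labelling protocols. Array medians of the 30 one-cycle arrays spanned 0.458 on the log2 scale, and their values were used as deposited. Medians of the 54 two-cycle arrays spanned 1.04, over the limit of 1, and their values were quantile normalized. Probe sets above the 40th percentile of all values in at least 3 arrays were tested, 20236 in the one-cycle and 19258 in the two-cycle arrays. Array signal is the mean of the unlogged values after trimming 2% at each end. Arrays have no read depth, so their number, 3 per group, limits the precision.

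Linear models with 1 coefficient per group and 1 shared spread per labelling protocol were fitted with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend. Each of 29 comparisons was tested two-sided with Benjamini-Hochberg adjustment over the probe sets tested in it, at an adjusted p of 0.05. By chance, 1012 one-cycle or 963 two-cycle probe sets would be expected at an unadjusted p under 0.05. A smaller number at that p is no sign of a response, and 0 calls beside it do not show that there was none. Standard errors (SE) are limma's moderated ones, and group values are means with the standard deviation (SD) of 3 arrays. Source names of all EpiC samples read continuous, so EpiC groups were taken from titles and descriptions. A single gene cannot reach an exact permutation p below 0.1 with 3 arrays against 3, so the tests rest on the spread shared across arrays and genes. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, where at least 3 members were measured. The adjusted p of a list covers all lists of its kind and 27 comparisons. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

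The comparisons, tests, filter, normalization limit, named-gene rule, 13 pathway lists, 7 marker lists and the first set of alternatives were fixed before the data were examined. By the named-gene rule, the text gives up to 6 genes with the largest rise and up to 6 with the largest fall per comparison. For the nitrate effect in a single sorted population or in protoplasts, the limit is 4 each way. The rule did not say whether this holds for MSX and glutamine in Peri, where up to 6 were given. Such a gene passed the test, had 1 gene and a symbol, and all arrays of 1 group lay beyond those of the other; for means over populations the direction held in all 5. F tests give the 6 smallest p. Members of the fixed lists may be named in any comparison, and a gene with several probe sets is represented by the one with the highest mean. Other genes named, bare locus identifiers and members of added lists among them, were chosen after their values were seen. Chosen after array quality, annotation or counts were seen were 19 further gene lists taken from the annotated symbols, the minimum of 3 members for camera, the nitrate index and the definition of arrays that stand apart. The nitrate index of an array is its mean log2 over 48 probe sets minus its mean over 39, which rose and fell in the mean continuous effect over the 5 sorted populations. It is circular for sorted arrays and independent of the one-cycle arrays. An array stands apart where its median correlation with the other one-cycle arrays is under 0.7, or with the other arrays of its sorted population under 0.6. This names 5 one-cycle and 2 two-cycle arrays, which stayed in the tests.

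The alternatives fixed beforehand were the other normalization, no filter, no intensity trend, only the arrays of the compared groups, the replicate number as a block, an estimated correlation, and each array left out in turn. Added after seeing the data were fits without the arrays that stand apart, with array weights (limma's arrayWeights, which did not converge), with both, with array signal as a covariate, and with the block on the compared arrays alone. Whether replicate numbers pair the arrays was checked from the data, since the labels do not say that a number marks a shared day or culture. Deviations from group means of same-numbered arrays correlated over 0.1 in every pair in whole roots at 3.5 h (0.677 to 0.818), continuous LRC (0.118 to 0.472), continuous EndoP (0.247 to 0.637) and the 2 KCl time points (0.109 to 0.198). With the block in the model of all arrays, the comparison of nitrate under MSX gave 1 probe set in place of 0.

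The steps were tested on simulated arrays with 200 changed probe sets. In these, each probe set varied independently and no array stood apart, unlike in the deposited arrays. The shares found and the false calls are therefore not error rates of the deposited data. For transitory nitrate in protoplasts (20236 probe sets), 2.99%, 29.9% and 81.8% of changes of 0.5, 1 and 2 log2 units were found, with 3 false calls. For continuous nitrate in EpiC (19258 probe sets) the shares were 0%, 2.99% and 75.8%, with 2 false calls. For the mean over the 5 populations they were 26.9%, 85.1% and 100%, with 6 false calls. For the F test of the populations in KCl they were 0%, 7.46% and 74.2%, with 1 false call.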

Results

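The series asks how root cell types respond to nitrate, and what digestion, sorting and a block of nitrogen assimilation do to that response. The 84 arrays covered 28 groups of 3. For each of the 5 sorted populations there were KCl, transitory nitrate and continuous nitrate groups, and for Peri also KCl with MSX, nitrate with MSX, and nitrate with MSX and glutamine. Unsorted protoplasts and incubated whole roots had the same 3 treatments, and whole roots frozen directly after treatment had KCl and nitrate at 2 h and at 3.5 h. Mean array signal was 71.2 to 84.7 on the one-cycle arrays and 169 to 372 on the two-cycle arrays. Median correlation with the other one-cycle arrays was 0.169 for whole roots in KCl at 2 h, replicate 1. It was 0.15 and 0.451 for incubated roots in KCl, replicates 1 and 2, and 0.678 and 0.103 for incubated roots in continuous nitrate, replicates 1 and 2. In the remaining one-cycle arrays it was 0.798 to 0.914. Among sorted arrays, LRC in continuous nitrate, replicate 1 (0.57), and EndoP in transitory nitrate, replicate 1 (0.47), stood apart from the rest of their populations, where the value was 0.642 to 0.951. The 3' to 5' difference of the GAPDH control probe sets, a sign of RNA quality, was 0.41 to 5.10 log2 units on the one-cycle and 2.23 to 6.38 on the two-cycle arrays. In 8 of 24 comparisons of 1 group with 1 group all arrays of the groups lay apart in it, where chance gives 10%, or 2.4; its values are given at those comparisons.

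**Figure D1:**
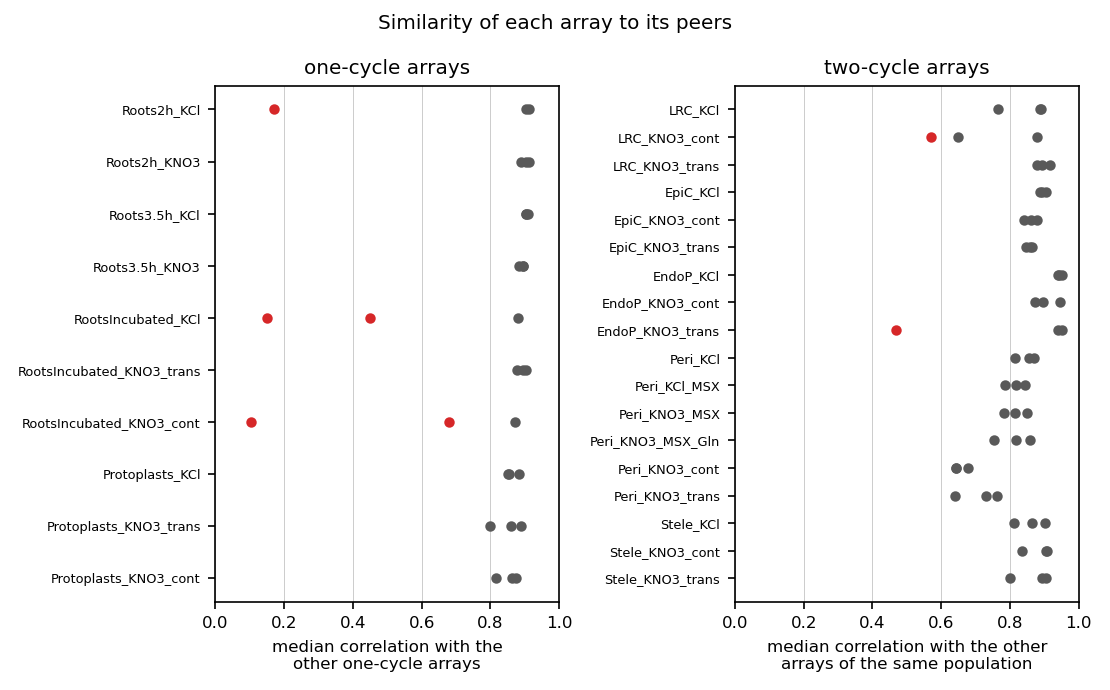
Median correlation of each array with the other one-cycle arrays (roots and protoplasts) or with the other arrays of its sorted population, 1 point per array, red where the array stands apart. The 5 red one-cycle points lie between 0.103 and 0.678 and the 2 red sorted points at 0.47 and 0.57.

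In KCl, the first question is what distinguishes the sorted populations. LRC held the highest levels of BGLU36 (AT1G51490), a beta-glucosidase (10.32 on the log2 scale, 4.06 above the mean of the other 4 populations, SE 0.35), and of SCPL34 (AT5G23210), a serine carboxypeptidase-like gene (4.55 above, SE 0.46). RCPG, a polygalacturonase of the root cap and the LRC marker fixed beforehand, was higher there by 2.27 (SE 0.50, adjusted p = 9.19e-04). Among genes named after their values were seen, RCA was higher in EpiC by 2.64 (SE 0.38) and LHCB4.2 by 2.52 (SE 0.40). OCT1 was higher in Peri by 3.39 (SE 0.46) and BCAT4 by 2.99 (SE 0.38). PORB, named in the same way, was higher both in Stele, by 2.88 (SE 0.73), and in EndoP, by 2.68 (SE 0.73). The nitrate regulators HHO1 to HHO3, GARP-family transcription factors, differed among the populations: HHO1 stood at 9.0 ± 0.21 (SD, n = 3) in LRC and between 5.63 and 6.17 in the other 4. By limma's F test 7922 of 19258 probe sets differed. Of those with a symbol, the smallest p were found for BGLU36 (adjusted p = 1.85e-10), HHP2 (AT4G30850, 1.20e-09), JAL33 (AT3G16450), CXE18 (AT5G23530), SCPL34 and scpl28 (AT2G35770, 1.18e-08). Adjusted p was 9.72e-04 for HHO1 and HHO2 and 0.00324 for HHO3. Of the other genes fixed beforehand, PGD2, cICDH, GI, GH3.3, LBD16, GSO1, EXPA7 and RCPG passed. Markers did not all follow the population names: EXPA7, an expansin of root hairs, was higher in EndoP by 1.98 (SE 0.66, adjusted p = 0.0352) and in Stele by 1.95 (0.0321), and its value in EpiC was -1.42 (0.198). GSO1, a receptor kinase of the endodermis, was lower in LRC by -1.98 (2.32e-04), with 1.14 in Peri (0.0918). The stele marker LHW passed in none of the populations. The 3 cortex markers JKD, AED3 and CO2, as a list, passed camera in none of the 27 comparisons (smallest adjusted p = 0.278), and adjusted p was 0.0275 for CO2 in LRC, higher by 0.59. Array signal in KCl was 236 to 277 in EndoP and 192 to 314 in Stele. It was 170 to 180 in LRC, 173 to 182 in EpiC and 173 to 176.5 in Peri. What sets EndoP and Stele apart, EXPA7 included, may therefore hold a difference in signal. The count was 3125 with array signal as a covariate.

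Averaged over the 5 populations, continuous nitrate raised PGD3 (AT5G41670) by 2.02 log2 units (SE 0.38, adjusted p = 0.00354) and PGD1 (AT1G64190) by 1.44 (SE 0.29, 0.00775), both 6-phosphogluconate dehydrogenases of the oxidative pentose phosphate pathway. HHO1 (AT3G25790) rose by 1.66 (SE 0.33, 0.00626). In each of the 5 populations these 3 genes had a higher mean in nitrate than in KCl. HHO3 rose by 0.78 (SE 0.17, 0.0166), though it was lower in Peri by -0.56, and HHO2 stood at 0.81 (SE 0.21, 0.0656). Chosen after their values were seen, AT1G80380 rose by 1.60 (SE 0.25, 3.14e-04), PGM (AT1G78050) by 1.12 (SE 0.23, 0.00843), and AT5G55050 fell by 1.15 (SE 0.18, 3.45e-04). Of 21 nitrate regulators fixed beforehand, HHO1, HHO2 and HHO3 can be named here; 2 of the 3 rose, and 3 when adjusted over the list alone. Camera gave an adjusted p of 1.95e-08 for this list (adjusted p = 0.00535 with an estimated correlation). Of 17 genes of nitrate reduction and reductant supply, PGD1, PGD2 and PGD3 can be named; 2 of 3 rose, and PGD2 stood at -0.37 (0.611), which fell when adjusted over the list alone. That list gave 0.00314 (adjusted p = 0.157 with an estimated correlation), so its call is lost. In limma 87 probe sets passed, 48 up and 39 down, against 1398 at an unadjusted p under 0.05. Of the 87, 35 moved the same way in all 5 populations. The count was 149 with only the compared arrays, 139 without LRC in KCl, replicate 2, 54 without LRC in KCl, replicate 3, 57 without EpiC in KCl, replicate 2, 55 without EndoP in KCl, replicate 3, 57 without Stele in KCl, replicate 3, and 52 without Stele in continuous nitrate, replicate 1. PGD3, HHO1, PGD1, HHO3, PGM, AT1G80380 and AT5G55050 passed in all of 39 alternatives, with adjusted p up to 0.0466 for HHO3.

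**Figure D2:**
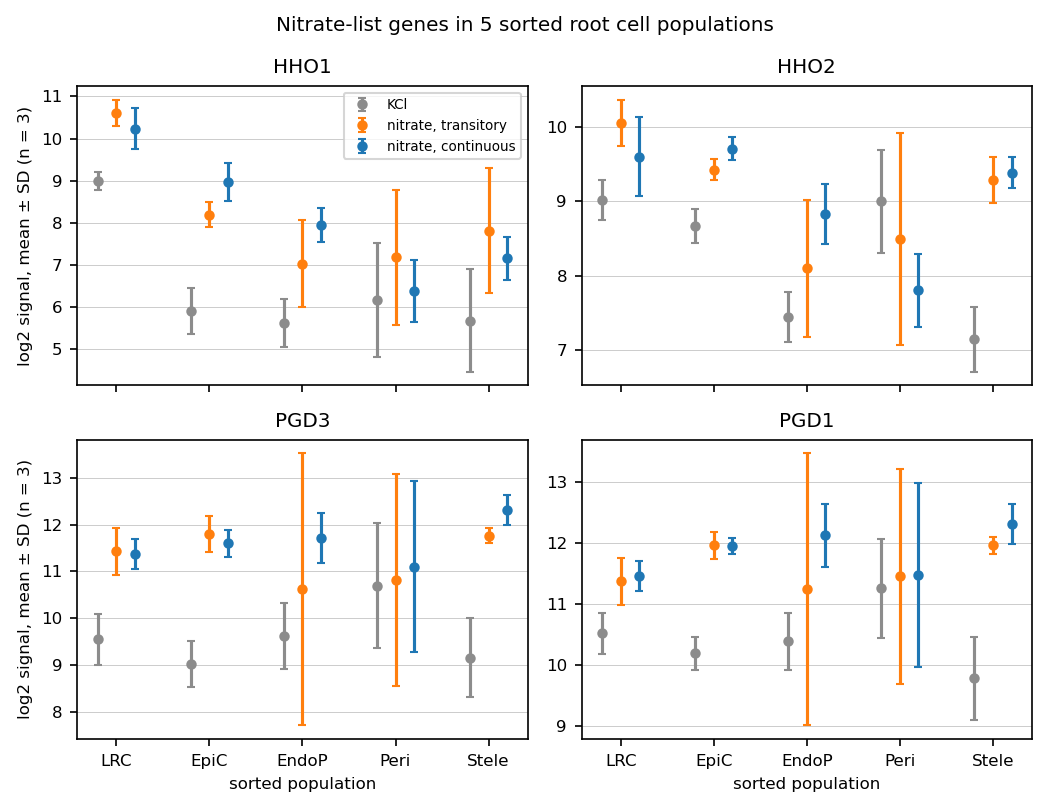
Log2 signal of HHO1, HHO2, PGD3 and PGD1 in the 5 sorted populations in KCl, transitory and continuous nitrate, as means with SD of 3 arrays. In continuous nitrate HHO1 stands at 8.96 ± 0.45 in EpiC against 5.89 ± 0.55 in KCl, and in Peri at 6.38 ± 0.73 against 6.17 ± 1.35.

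Whether the populations differ in this response was tested with an F test of the interaction. Of 17 genes fixed beforehand that were looked at, HHO2 and STZ had differences of opposite sign with all arrays of each group apart: HHO2 stood at 2.25 in Stele, 1.38 in EndoP, 1.04 in EpiC and -1.20 in Peri, with an adjusted p of 0.0726, the smallest found, and STZ at 0.47 in Stele and -1.06 in Peri (0.189). Array signal was higher in nitrate than in KCl in Peri and not in Stele, and its part in these signs stays open. No probe set passed in limma, against 5114 at an unadjusted p under 0.05, where 963 would be expected by chance. The count was 3523 without LRC in continuous nitrate, replicate 2, 1878 without Stele in KCl, replicate 1, 1543 without Peri in continuous nitrate, replicate 3, 1175 without EndoP in continuous nitrate, replicate 2, 5 without EpiC in continuous nitrate, replicate 3, and 2 without LRC in KCl, replicate 3. Over the other alternatives it ranged from 0 to 3560, and with array weights it was 16295. Continuous and transitory treatment, compared over the 5 populations, differed in 0 probe sets in limma, with 183 at an unadjusted p under 0.05, and in 0 by each of 39 alternatives.

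In EpiC, continuous nitrate raised HHO1 by 3.07 (SE 0.74, adjusted p = 0.0359), from 5.89 ± 0.55 to 8.96 ± 0.45 (SD, n = 3), and PGM by 2.7 (SE 0.51, 0.00302), from 7.53 ± 0.17 to 10.23 ± 0.33. Genes of photosynthesis fell. PSAE-1 (AT4G28750), a subunit of photosystem I, fell by 3.21 (SE 0.67, 0.0074) to 6.70 ± 0.10, and PSBW (AT2G30570), of photosystem II, by 2.85 (SE 0.57, 0.00539). RCA (AT2G39730), Rubisco activase, fell by 2.73 (SE 0.48, 0.00178) from 9.83 ± 0.36 to 7.10 ± 0.21, and PSAN (AT5G64040), of photosystem I, by 2.62 (SE 0.63, 0.0338). Of 13 nuclear photosynthesis genes, a list drawn up after the annotation was seen, 9 fell, with a median of -2.54 and camera adjusted p = 5.43e-48 (adjusted p = 5.22e-05 with an estimated correlation). Besides these 4 they were ATPC1, LHCB4.1, LHCB4.2, PRK and SBPASE, named after their values were seen, and PSBY, PSB27, PORB and LHCB4.3 did not pass. In KCl, RCA had been higher in EpiC than in the other 4 populations by 2.64, LHCB4.2 by 2.52, PRK by 2.48, PSAE-1 by 2.47 and LHCB4.1 by 2.22. Falls in both nitrate treatments were measured against these same 3 KCl arrays. Of 6 markers of green shoot tissue fixed beforehand, 0 can be named here. Whether the KCl arrays held more green tissue was therefore not tested. The 3 nitrate regulators gave camera adjusted p = 9.59e-08 (adjusted p = 0.00585 with an estimated correlation); 1 rose, and 3 when adjusted over the list alone. PGD3 stood at 2.58 (0.348) and PGD1 at 1.76 (0.598). Nitrate reduction and reductant supply gave 0.00993 (adjusted p = 0.227 with an estimated correlation). Chosen after their values were seen, the loci AT1G80380, AT1G59740 and AT2G48080 rose by 2.96, 2.69 and 2.16. In limma 94 probe sets passed, 26 up and 68 down, against 650 at an unadjusted p under 0.05. The GAPDH 3' to 5' difference was 2.575 to 3.485 in nitrate and 3.498 to 4.124 in KCl. The count was 25 without KCl replicate 2, 51 without KCl replicate 3 and 46 without nitrate replicate 1. HHO1 lost its call on leaving out any of the 6 arrays (adjusted p 0.0799 to 0.254), and PSAN on leaving out any but KCl replicate 1. Without KCl replicate 2, PSAE-1 (0.0952), PSBW (0.0620) and the 5 others of the photosynthesis list (0.0522 to 0.159) did not pass. PSAE-1, LHCB4.1, LHCB4.2 and PRK did not pass without nitrate replicate 1 either, nor LHCB4.2 without KCl replicate 3, while PGM, RCA and the 3 loci passed in all of 15 alternatives.

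Under transitory nitrate in EpiC the photosynthesis gene PSAE-1 fell by 3.01 (SE 0.67, adjusted p = 0.0271), PSBW fell by 2.59 (0.0266), ATPC1 (AT4G04640), a subunit of the plastid ATP synthase, fell by 2.49 (0.0102), and LHCB4.1 (AT5G01530), a light-harvesting protein, fell by 2.46 (0.0237). Of the 13 nuclear photosynthesis genes 8 fell, RCA, PRK, SBPASE and LHCB4.2 being the others, with a median of -2.24 and camera adjusted p = 1.26e-46 (adjusted p = 5.22e-05 with an estimated correlation). These 8 each lost the call on leaving out at least 3 of the 6 arrays. HHO1 stood at 2.3 (0.488) and PGM at 2.03 (0.0710). For the nitrate regulators camera gave 4.74e-05 (adjusted p = 0.0306 with an estimated correlation); 0 rose, and 1 when adjusted over the list alone. Chosen after their values were seen, AT1G59740 rose by 2.49 and AT5G55050 fell by 2.44 (0.00428 each). In limma 58 probe sets passed, 9 up and 49 down. All 9 that rose also rose in continuous nitrate, where 0.0122 shared ones would be expected of independent lists, and 43 that fell fell in both, against 0.173. The effects correlated across genes at 0.664, where unchanged groups against shared controls gave 0.499 in 100 simulations, and their covariance was 0.0964 against a simulated 0.105. Part of the overlap may come from the 3 shared KCl arrays, which cannot be split into groups of 2. The count was 5 without KCl replicate 2, 7 without KCl replicate 3, 3 without nitrate replicate 2 and 0 without nitrate replicate 3. With only the EpiC transitory and KCl arrays it was 27, of which 20 rose, 74.1% against 15.5% with all sorted arrays.

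**Figure D3:**
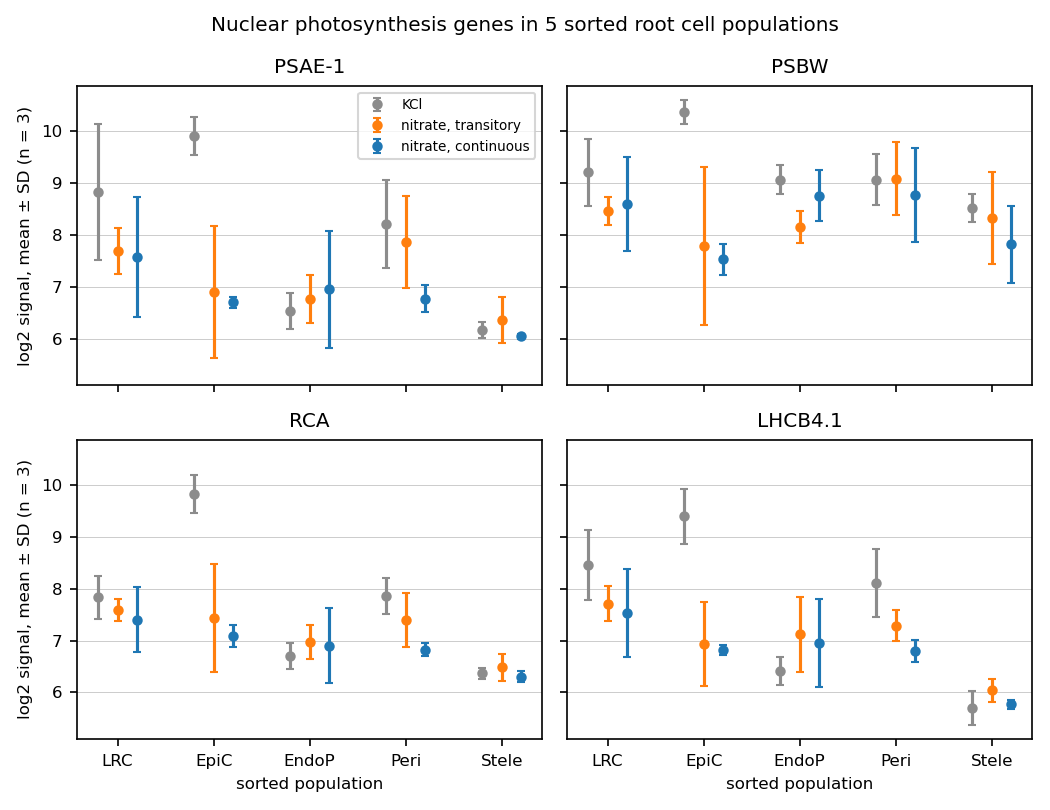
Log2 signal of PSAE-1, PSBW, RCA and LHCB4.1 in the 5 sorted populations in KCl, transitory and continuous nitrate, as means with SD of 3 arrays. In EpiC, PSAE-1 stands at 9.91 ± 0.37 in KCl, 6.90 ± 1.27 in transitory and 6.70 ± 0.10 in continuous nitrate.

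In Stele under continuous nitrate, PGD3 stood 3.17 above KCl (adjusted p = 0.386), PGD1 2.53 (0.31), HHO2 2.25 (0.117), HHO3 1.98 (0.112) and SIR, the sulfite reductase gene, 1.64 (0.484). The nitrate regulators passed camera in both treatments, continuous (1.33e-05, adjusted p = 0.0204 with an estimated correlation) and transitory (1.12e-06, adjusted p = 0.0108 with an estimated correlation); adjusted over the list alone, 2 and 3 of them rose. Nitrate reduction and reductant supply gave 0.00265 in continuous nitrate (adjusted p = 0.157 with an estimated correlation). In transitory nitrate HHO3 stood at 2.06 (0.0563) and HHO2 at 2.14. In limma 0 probe sets passed in either treatment, against 1986 and 1968 at an unadjusted p under 0.05. For continuous nitrate 6 passed without KCl replicate 1, and 8, HHO2, HHO3 and PGD1 among them, without the sorted arrays that stand apart, neither of which is from Stele; the range was 0 to 8, and 12657 with array weights. For transitory nitrate 80 passed without KCl replicate 1 and 21 without nitrate replicate 1, the range was 0 to 80, and array weights gave 12039. Signal in KCl was 192 to 314.

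In EndoP under continuous nitrate, HHO1 stood at 7.95 ± 0.41 against 5.63 ± 0.57 in KCl (SD, n = 3), PGD3 2.1 above KCl, PGD1 1.74 and HHO2 1.38. The nitrate regulators gave 5.42e-09 (adjusted p = 0.00535 with an estimated correlation), with 0 rising and 3 when adjusted over the list alone. In transitory nitrate, where replicate 1 stands apart, they gave 0.0258 (adjusted p = 0.249 with an estimated correlation). By limma's test 0 probe sets passed in either treatment, against 189 and 1010 at an unadjusted p under 0.05, where chance gives 963. The range over alternatives was 0 to 7 for continuous nitrate and 0 to 0 for transitory nitrate, and array weights gave 4690 and 143.

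In LRC under continuous nitrate, where replicate 1 stands apart, PGD3 stood 1.83 above KCl (adjusted p = 0.335) and HHO1 1.24 (0.398), and HHO1 was already high in KCl, at 9.0 ± 0.21 (SD, n = 3). For the nitrate regulators camera gave 0.126. Limma called 0 probe sets, against 2766 at an unadjusted p under 0.05. With the replicate number as a block and only these arrays, 56 passed, 48 up and 8 down. PGD3 then rose by 1.89 (3.64e-04), and MT1C, a metallothionein gene chosen after its values were seen, by 2.67. The count was 51 without KCl replicate 2, 1 without KCl replicate 3 and 2635 without nitrate replicate 2, with 0 to 2635 over alternatives. Transitory nitrate raised 2 probe sets in LRC, AT5G26200, by 1.96 (SE 0.35, 0.0337), chosen after its value was seen, and an unnamed one by 2.34 (0.0396); 779 had an unadjusted p under 0.05, and with only the compared arrays 0 passed. Both also rose in EpiC in continuous nitrate, where 0.0027 shared ones would be expected of independent lists. The nitrate regulators gave 6.39e-04 (adjusted p = 0.0815 with an estimated correlation), and 3 of 3 rose when adjusted over the list alone. The count was 1, 44 and 5 without KCl replicates 1, 2 and 3, and 0, 5 and 0 without nitrate replicates 1, 2 and 3. AT5G26200 did not pass without KCl replicate 3 (0.0518) or nitrate replicates 1 (0.102) and 3 (0.538).

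In Peri under continuous nitrate the largest falls among genes with a symbol were in OCT1 (AT1G73220), an organic cation transporter, by 2.79 (SE 0.58, adjusted p = 0.0168) from 10.53 ± 1.13 to 7.74 ± 0.61 (SD, n = 3), AR781 (AT2G26530) by 2.69, rpl32 (ArthCp072), a plastid-encoded ribosomal protein, by 2.59, and UGT71C1 (AT2G29750), a glycosyltransferase, by 2.55. The largest rises among these were in AGL91 (AT3G66656), a MADS-box gene, by 2.54 (SE 0.62, 0.0178), HEMA3 (AT2G31250), a glutamyl-tRNA reductase, by 2.48 (SE 0.55, 0.0168), TRY (AT5G53200), a MYB factor of epidermal patterning, by 2.35 and AtS40-3 (AT4G18980) by 2.33. The nitrate genes stood at 0.41 for PGD3, 0.21 for HHO1 and -1.20 for HHO2 (0.0597), and the nitrate regulators gave camera adjusted p = 0.443, with 1 falling when adjusted over the list alone. Of other genes fixed beforehand, GH3.3, an auxin-conjugating enzyme, fell by 1.53 (0.0375), and the cortex marker JKD and the root hair expansin EXPA18 rose by 1.51 (0.0356) and 1.25 (0.0431). In a list added after the annotation was seen, 7 of 10 autophagy genes fell, APG8A by 2.16 and ATG8F by 1.70 among them, with camera adjusted p = 6.07e-04 (adjusted p = 0.722 with an estimated correlation). Of 3525 probe sets that passed in limma 1819 rose and 1706 fell. Array signal moved with the treatment: it was 173 to 177 in KCl and 205 to 372 in continuous nitrate. With signal as a covariate 8 probe sets passed, OCT1 among them, which fell by 3.21 (SE 0.66, 0.044). Without normalization 5919 passed, 95.9% of them up against 51.6%, and the median of all probe sets was 0.44 against -0.13. On leaving out each of the 6 arrays in turn, OCT1 and UGT71C1 passed 5 times (not without KCl replicate 3, 0.0628 and 0.0645), HEMA3, AR781 and APG8A 4 times, AGL91 and ATG8F 3 times, TRY, rpl32 and JKD 1 time and AtS40-3, GH3.3 and EXPA18 0 times. The count was 19 without KCl replicate 1, 2 without KCl replicate 3, and 697 and 318 without nitrate replicates 1 and 2.

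Transitory nitrate in Peri raised TET14 (AT2G01960), a tetraspanin gene, by 1.34 (SE 0.25, adjusted p = 0.0299), from 5.59 ± 0.42 to 6.93 ± 0.60 (SD, n = 3). For the nitrate regulators camera gave 0.97, HHO1 standing at 1.01 and PGD3 at 0.13. In limma 13 probe sets passed, 10 up and 3 down, against 5490 at an unadjusted p under 0.05, and with only the compared arrays 2 passed. Of these, 9 rose and 3 fell in continuous nitrate too, where 0.945 and 0.266 would be expected of independent lists. The effects correlated across genes at 0.894 against a simulated 0.499, with a covariance of 0.686 against 0.105, and part of the overlap may come from the shared KCl arrays. Signal was 177 to 353 in this group, and with signal as a covariate 0 passed. Without normalization 2357 passed, 99.2% of them up against 76.9%, and the median of all probe sets was 0.39 against -0.13. The count was 0, 0 and 1 without KCl replicates 1, 2 and 3, and 2, 0 and 4181 without nitrate replicates 1, 2 and 3. TET14 did not pass without KCl replicate 1 (0.213), KCl replicate 2 (0.107) or nitrate replicate 2 (0.0606).

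The MSX samples ask which responses need assimilation of nitrogen by glutamine synthetase. In Peri with MSX, nitrate gave PGD3 values of 12.17 ± 0.12 against 9.67 ± 0.04 in KCl (SD, n = 3), a difference of 2.5, and HHO1, PGM and PGD1 stood 1.83, 1.82 and 1.60 higher. None passed over all genes, and 2 of the 3 genes of nitrate reduction and reductant supply rose when adjusted over the list alone; camera gave 0.0198 for that list (adjusted p = 0.249 with an estimated correlation) and 0.0167 for the nitrate regulators (adjusted p = 0.23 with an estimated correlation). In limma 0 probe sets passed, the smallest adjusted p being 0.0507, against 275 at an unadjusted p under 0.05, where chance gives 963. With only these arrays 14 passed, and PGD3 rose by 2.53 (0.00442) and PGD1 by 1.55 (0.0289); the range was 0 to 14, and 67 with array weights. Whether MSX changed the nitrate effect was tested as an interaction: PGM stood at 2.32 and PGD3 at 2.09 (0.648 each), 0 probe sets passed in limma, 1457 had an unadjusted p under 0.05, and the count was 0 by every alternative but array weights (8595 and 8525). Signal was 169 to 174 in KCl with MSX and 175 to 289 in nitrate with MSX, and the GAPDH 3' to 5' difference 4.05 to 4.40 and 3.16 to 3.84.

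Without nitrate, MSX raised SUFE2 (AT1G67810), an activator of cysteine desulfurase, by 1.92 (SE 0.41, adjusted p = 0.0435), from 8.05 ± 0.49 to 9.97 ± 0.16 (SD, n = 3). Chosen after their values were seen, AT4G37180 fell by 2.02 (SE 0.32, 0.00237) and AT5G19120 by 2.33 (SE 0.48, 0.0371). No gene fixed beforehand passed, with HHO1 at 1.33 and NRT2.5, the only one of 16 nitrate transport genes that can be named, at 0.51 (0.680). In limma 13 probe sets passed, 6 up and 7 down, against 1537 at an unadjusted p under 0.05, and with only the compared arrays 1 passed. More passed without normalization, without the arrays that stand apart and with array signal as a covariate. The GAPDH 3' to 5' difference was 4.05 to 4.40 with MSX and 2.56 to 3.13 without. The count was 3 and 8 without KCl replicates 1 and 2, and 2, 2 and 8 without MSX replicates 1, 2 and 3. AT4G37180 passed without each of the 6 arrays, SUFE2 lost its call on leaving out any but KCl replicate 3, and AT5G19120 on leaving out any.

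Glutamine added to nitrate and MSX raised HRA1 (AT3G10040), a trihelix transcription factor of the low-oxygen response, by 2.83 (SE 0.70, adjusted p = 0.0383), from 6.75 ± 0.61 to 9.58 ± 0.57 (SD, n = 3). MSRB5 (AT4G04830), a methionine sulfoxide reductase, rose by 2.56 (SE 0.61, 0.0287), ATSBT5.2 (AT1G20160), a subtilase, by 1.74, and NRPB9B (AT4G16265), a subunit of RNA polymerase II, by 1.16. GH3.1 (AT2G14960), of the auxin-conjugating family, fell by 2.00 (SE 0.45, 0.0193), SDH1-2 (AT2G18450), a subunit of succinate dehydrogenase, by 1.86 (SE 0.42, 0.0212), the glycosyltransferases UGT76D1 (AT2G26480) and UGT73B5 (AT2G15480) by 1.8 and 1.68, and PRXR1 (AT4G21960), a peroxidase, by 1.38. Of 41 glycosyltransferases, a list added after the annotation was seen, these 2 fell, with camera adjusted p = 6.72e-05 (adjusted p = 0.722 with an estimated correlation). Chosen after their values were seen, AT4G15690 rose by 4.03 (SE 0.48, 1.22e-06) and AT3G15450 by 3.68 (SE 0.57, 3.25e-04), and both passed in all of 15 alternatives. HHO1 stood at -2.13 (0.169), LDH1, the other named gene of the low-oxygen list, did not pass, and the nitrate regulators gave 0.97. In limma 134 probe sets passed, 70 up and 64 down. With only the compared arrays 26 passed, and without normalization 228, 39.9% of them up against 52.2%. The count was 15 and 27 without MSX replicates 1 and 2, and 26, 238 and 36 without glutamine replicates 1, 2 and 3; the genes named by symbol passed on leaving out 0 to 3 of the 6 arrays. Signal was 175 to 289 without and 188 to 211 with glutamine, and the GAPDH 3' to 5' difference 3.16 to 3.84 and 3.97 to 5.33.

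In unsorted protoplasts, HHO1 stood at 5.77 ± 0.62 in KCl, 7.33 ± 0.33 in transitory and 7.35 ± 0.27 in continuous nitrate (SD, n = 3). HHO3 was 1.05 and 1.11 higher in transitory and continuous nitrate, and PGD3 1.74 and 1.55. The nitrate regulators passed camera in both, with 3.23e-10 in transitory (adjusted p = 0.00585 with an estimated correlation) and 2.97e-08 in continuous nitrate (adjusted p = 0.0145 with an estimated correlation); adjusted over the list alone 3 and 2 of them rose. The auxin and lateral root list, with GH3.3, LBD16, LBD29 and WES1, was lower in continuous nitrate (0.00419, adjusted p = 0.157 with an estimated correlation). By limma's test 0 probe sets passed in either treatment, against 178 in transitory and 442 in continuous nitrate at an unadjusted p under 0.05. By chance 1012 would be expected. In continuous nitrate 6 passed without KCl replicate 2 and 13 without nitrate replicate 2, the range was 0 to 13, and array weights gave 221. In transitory nitrate the count was 0 by each of 15 alternatives. The treatments differed from each other in 0 probe sets in limma, with 19 at an unadjusted p under 0.05 and 0 by each of 15 alternatives. Their effects against the shared controls correlated across genes at 0.783, against a simulated 0.499, with a covariance of 0.0472 against 0.0625.

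In whole roots at 2 h, PGD3 stood 1.71 above KCl (SE 1.03), PGD1 1.60 (SE 0.94), HHO1 1.04 (SE 0.38), HHO2 0.70 and HHO3 0.54, each at an adjusted p of 0.785. In KCl, PGD3 had a value of 7.68 ± 2.39 (SD, n = 3). The nitrate regulators gave camera adjusted p = 0.00145 (adjusted p = 0.157 with an estimated correlation), with 0 rising and 1 when adjusted over the list alone, and nitrate reduction and reductant supply gave 0.00923 (adjusted p = 0.241 with an estimated correlation). The nitrate index was 1.04 ± 1.32 in KCl, with 2.56 in replicate 2, the highest of the 30 one-cycle arrays and above each of the 3 nitrate arrays at 2 h, and 1.67 ± 0.20 in nitrate. Limma called 0 probe sets, and 237 had an unadjusted p under 0.05, where chance gives 1012. The count was 0 by every alternative but array weights (928). At 3.5 h PGD3 stood at 0.16 and HHO1 at -0.23, and the nitrate index was 1.57 ± 1.15 in KCl and 1.62 ± 1.09 in nitrate. It was 1.89 to 2.29 in replicates 1 and 2 of both groups, and of incubated roots in transitory nitrate, and 0.21 to 0.37 in their replicates 3. In limma 0 probe sets passed, and 25 had an unadjusted p under 0.05, where chance gives 1012. The count was 0 by each of 16 alternatives, those with the replicate number as a block among them.

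**Figure D4:**
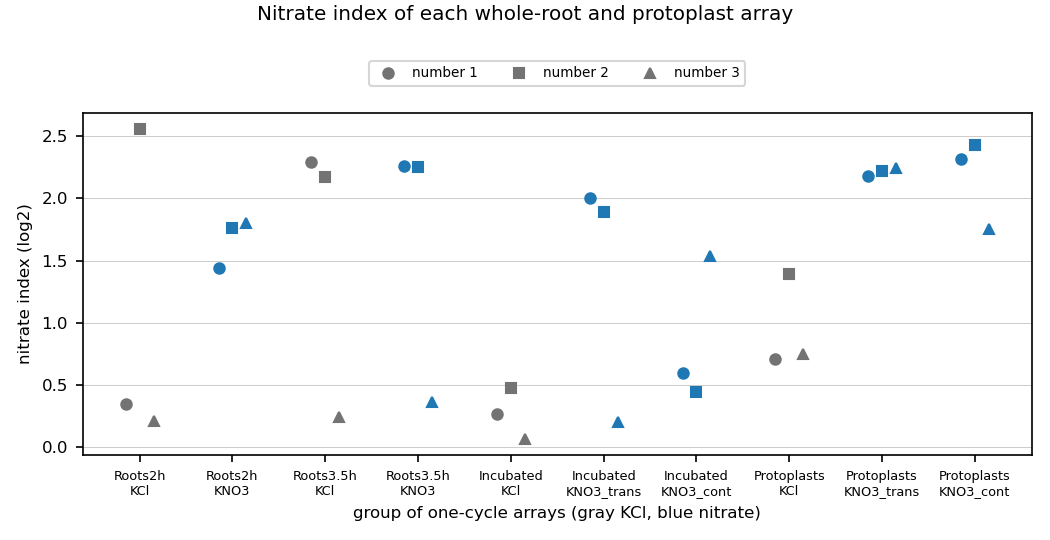
Nitrate index of each one-cycle array, the mean log2 of 48 probe sets minus that of 39 which rose and fell in sorted cells, with markers showing the replicate number. In protoplasts the index is 0.95 ± 0.38 in KCl and 2.17 ± 0.36 in continuous nitrate, while at 3.5 h it is 0.25 in KCl replicate 3 and 0.37 in nitrate replicate 3.

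In incubated whole roots, transitory nitrate raised PGD3 by 3.37 (SE 1.03, adjusted p = 0.0361), from 5.97 ± 0.90 to 9.33 ± 1.24 (SD, n = 3), PR-1-LIKE (AT2G19990), a pathogenesis-related gene, by 3.35 (SE 0.81, 0.0281), SAMDC (AT3G02470), an enzyme of polyamine synthesis, by 2.66, UGT76B1 (AT3G11340) by 2.58, DI19 (AT1G56280), a drought-induced gene, by 2.29 and APS4 (AT5G43780), an ATP sulfurylase, by 2.17. GILT (AT4G12960) fell by 2.47, SPCH (AT5G53210), a factor of the stomatal lineage, by 2.34, psaC (ArthCp075), of photosystem I, by 2.29 (SE 0.45, 0.0261), YAB5 (AT2G26580) by 2.25, AtS40-3 by 2.19 and atpI (ArthCp010), of the plastid ATP synthase, by 2.06. Of other genes fixed beforehand, SIR, LDH1, WES1 and LBD29 rose and WRKY53 fell. Of 69 plastid-encoded genes, a list added after the annotation was seen, 22 fell, with camera adjusted p = 5.94e-05 (adjusted p = 0.863 with an estimated correlation). HHO1 stood at -0.20, and the nitrate regulators gave 0.406. The nitrate index was 0.27 ± 0.21 in KCl and 1.37 ± 1.01 in transitory nitrate. In limma 4964 probe sets passed, 1936 up and 3028 down, and with only the compared arrays 1 passed. The GAPDH 3' to 5' difference was 0.412 to 1.05 in transitory nitrate and 2.49 to 3.66 in KCl. KCl replicates 1 and 2 are among the arrays that stand apart, and without these arrays, which leaves 1 KCl array, 0 passed. The count was 0, 0 and 11261 without KCl replicates 1, 2 and 3, and 194, 0 and 0 without nitrate replicates 1, 2 and 3, and each named gene passed on leaving out at most 2 of the 6 arrays.

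Continuous nitrate in incubated roots, where replicates 1 and 2 of both groups stand apart, gave PGD3 a value of 7.27 ± 2.15 and HHO1 of 5.87 ± 0.12 against 5.31 ± 0.44 in KCl (SD, n = 3). For the nitrate regulators camera gave an adjusted p of 6.40e-04 (adjusted p = 0.157 with an estimated correlation). By limma's test 0 probe sets passed, against 46 at an unadjusted p under 0.05, with 0 to 1 over alternatives and 11636 with array weights. Continuous against transitory nitrate, psaC was higher by 2.68 (SE 0.45, adjusted p = 0.0131), GILT by 2.68, the plastid ribosomal proteins rpl16 (ArthCp060) and rpl14 (ArthCp059) by 2.57 and 2.46, SPCH by 2.54 and YAB5 by 2.49. Lower values were found for PR-1-LIKE, at -3.77 (SE 0.81, 0.0226), UGT76B1 at -2.60, UGT72E2 (AT5G66690) at -2.27, UGT71C1 at -2.02, LDH1 (AT4G17260), a lactate dehydrogenase, at -1.97, and EXPB2 (AT1G65680), an expansin, at -1.94. Of the 69 plastid-encoded genes 35 were higher (camera adjusted p = 1.63e-09, adjusted p = 0.787 with an estimated correlation). In limma 4098 probe sets differed, 2698 up and 1400 down, and with quantile normalization 1406, 36.3% of them up against 65.8%, and with only the compared arrays 2418. The GAPDH 3' to 5' difference was 1.82 to 5.10 in continuous and 0.412 to 1.05 in transitory nitrate. Without the arrays that stand apart, which leaves 1 continuous array, 3 passed. The count was 210, 0 and 0 without transitory replicates 1, 2 and 3, and 2, 24 and 8317 without continuous replicates 1, 2 and 3, and here too each named gene passed on leaving out at most 2 arrays.

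The KCl groups also ask what the handling does. Incubation in the solution was compared with whole roots at 3.5 h. The genes psaC, AtS40-3, psbB (ArthCp049), YAB5, rpl16 and atpI were higher after incubation by 2.15, 2.07, 2.07, 2.02, 1.98 and 1.95, with an adjusted p of 0.0376 for psaC. PR-1-LIKE was lower by -3.96 (SE 0.81, 0.0376), PGD3 by -3.66 (SE 1.03, 0.0429), UGT72E2 by -2.47, LDH1 by -2.43, DI19 by -2.27 and TIL (AT5G58070), a lipocalin gene, by -2.14. Of genes fixed beforehand SIR, WES1 and LBD29 fell too, and nitrate reduction and reductant supply was lower (0.0258, adjusted p = 0.284 with an estimated correlation). The GAPDH 3' to 5' difference was 2.49 to 3.66 after incubation and 0.467 to 1.08 at 3.5 h. In limma 3927 probe sets differed, 2365 up and 1562 down; 0 passed without the arrays that stand apart or with quantile normalization, and 1 with only the compared arrays. The count was 0, 0 and 11409 without incubated replicates 1, 2 and 3, and 0 without each of the replicates 1, 2 and 3 at 3.5 h. On leaving out each of the 6 arrays in turn, the named genes passed without incubated replicate 3 and not without any other. The nitrate index in KCl was 0.27 ± 0.21 after incubation and 1.57 ± 1.15 at 3.5 h, with 2.29 and 2.17 in replicates 1 and 2 and 0.25 in replicate 3.

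Digestion was compared as protoplasts against incubated roots in KCl. Per the labels' protocols these groups also differ in RNA purification, by columns against TRIzol, and protoplasts were held on ice. These differences cannot be told apart from digestion here. Incubated replicates 1 and 2 stand apart, with median correlations of 0.15 and 0.451. PGD1 stood 1.52 higher and HHO1 0.46 higher, and the nitrate regulators gave 0.443. The GAPDH 3' to 5' difference was 0.958 to 2.04 in protoplasts and 2.49 to 3.66 in incubated roots. Limma called 0 probe sets, the smallest adjusted p being 0.0727, against 6843 at an unadjusted p under 0.05. The count was 1275 without protoplast replicate 3 and 9974 without incubated replicate 3, with 0 to 9974 over alternatives and 14833 with array weights. From 2 h to 3.5 h in KCl, rpl16 differed by -2.7 (adjusted p = 0.102), and the nitrate regulators gave 0.208. In limma 0 probe sets passed, against 2246 at an unadjusted p under 0.05. With only these arrays rpl16 passed (0.0115), and it passed with the replicate number as a block too (0.0265), 1 probe set in each case. Without KCl replicate 2 at 2 h the count was 2, over alternatives 0 to 2, and with array weights 8396.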

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

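For the Peri calls and the transitory calls in incubated roots, the tests were written down before their shares were computed, but after array correlations, array signal and the counts with altered models had been seen; the tests on the 9 whole-root arrays were chosen after the result was seen, and those on RNA quality and on probe sets outside the index after the other shares had been seen.

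HHO2 and STZ, 2 of 17 genes fixed beforehand that were looked at, had differences of opposite sign in different populations under continuous nitrate, with all arrays of each group apart. HHO2 stood at 1.04 in EpiC, 1.38 in EndoP, 2.25 in Stele and -1.20 in Peri, and the F test of the difference among the populations missed the threshold (adjusted p = 0.0726). STZ stood at -1.06 in Peri and 0.47 in Stele (0.189). Chance sets the arrays of 3 against 3 apart in 10% of comparisons, and each gene was looked at in 5 populations. In Peri, where both were lower, array signal was 173 to 176.5 in KCl and 205 to 372 in continuous nitrate. In Stele, where both were higher, it was 192 to 314 in KCl and 179 to 213.5 in continuous nitrate. Whether array signal accounts for the opposite signs stays open.

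Continuous nitrate in Peri gave 3525 calls, more than in any other sorted population, and 0 to 94 in those. A nitrate response that needs no glutamine synthetase and leaves array signal low was argued against as the source of most of these calls. Under MSX, with nitrate replicates 1 and 3, which have low signal, 0.522 of the called probe sets moved the same way. For such a response 0.75 or more was set down, and 0.55 or less against it. Of the probe sets not called, 0.483 moved so. Nitrate with MSX, replicate 2, has a high signal (289) and was left out. A response without glutamine synthetase that comes with higher signal was therefore not tested. The GAPDH 3' to 5' difference also lay apart, at 3.16 to 3.84 in nitrate with MSX and 4.05 to 4.40 in KCl with MSX. Under MSX, PGD3 and PGD1 stood 2.5 and 1.60 higher in nitrate, neither past the threshold with all sorted arrays. The share therefore does not show that nitrate responses in Peri need glutamine synthetase. An effect of array signal may account for most of the calls, since 0.965 of them had the same sign between arrays of high and low signal within groups that are not part of the comparison (0.969 within nitrate with MSX, 0.885 within Stele in KCl), though 0.83 of the probe sets not called did so too. With signal in the model, the median size of the 3525 changes went from 1.5 (median SE 0.46) to 0.56 (0.43) with 3306 keeping their sign, so the calls ended because the changes shrank and not because the errors grew. A nitrate response that itself raises array signal, whether or not it needs assimilation, was not tested and stays open. So do the 8 calls made with signal in the model.

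Transitory nitrate in incubated roots gave 4964 calls and continuous nitrate 0. Arrays that stand apart could account for these calls: 0.987 of them had the same sign in whole roots in KCl at 2 h between the arrays that do not stand apart and the one that does (0.846 of the probe sets not called). A difference between sets of arrays processed together could do so as well. Between nitrate roots at 3.5 h and at 2 h 0.937 had the same sign (0.601 of those not called). These 2 groups also differ in treatment time, so that share cannot be assigned to a set of arrays alone. The transitory group shares low hybridization controls with the 3.5 h groups. CreX was 10.7 to 11.3 there, against 11.3 to 12.3 on the other 21 one-cycle arrays. BioB was 6.04 to 6.49 against 6.83 to 9.22. RNA quality could too: the 3' to 5' difference of GAPDH was 0.412 to 1.05 in the transitory and 2.49 to 3.66 in the KCl group, and 0.924 of the calls had the same sign between arrays of low and high difference within 2 other groups (0.678 of the probe sets not called), though this was 0.938 in protoplasts in continuous nitrate and 0.501 in whole roots in nitrate at 2 h. Without the arrays that stand apart, which leaves 1 KCl array, the median size of 3822 of these changes went from 1.08 (median SE 0.33) to 0.44 (0.31), with 3768 keeping their sign, and none was called. With only the arrays of the compared groups 1 was called, in a fit that leaves the differences as they are and changes only their errors and the probe sets tested, so this bears on none of the explanations. A nitrate response of incubated roots was not tested apart from these and stays open.

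The 9 arrays of whole roots at 3.5 h in KCl and in nitrate and of incubated roots in transitory nitrate followed their replicate number and not their group. Correlations were 0.979 to 0.993 between arrays of the same number and 0.942 to 0.983 between arrays of the same group, and the 9 arrays fitted alone gave 0 calls by group and 3759 by number, of 14332 probe sets. In the nitrate index, no response at 3.5 h as labelled was seen. It differed between nitrate and KCl by -0.03, 0.08 and 0.12 within numbers 1, 2 and 3, 0.055 on average. The bounds, 1 or more for such a response and 0.2 or less against it, were set down after the index had been seen. The index holds 87 probe sets chosen in sorted cells, so it does not test a response of other genes at 3.5 h. An interchange of group and number in the labels stays open. Of 87 index probe sets 80, a share of 0.92, differed between numbers 1 and 2 and number 3 as under nitrate in sorted cells. These probe sets were chosen without the 9 arrays, so the numbers do differ in the direction of the nitrate effect. That test was written after the index had been seen to differ by number, so it cannot decide the cause. Outside the index, 1311 probe sets had an unadjusted p under 0.05 in sorted cells. Of these, 0.674 differed by number as under nitrate (0.535 of the others). This share lies between the 0.75 set down for an interchange and the 0.5 against it. An interchange would make the 3 arrays numbered 3 the KCl group and those numbered 1 and 2 the nitrate groups, which no label states. The transitory group of incubated roots would then hold arrays of other groups. Its 4964 calls, and the 4098 of continuous against transitory nitrate, would change their meaning. A batch or an RNA quality shared by the arrays of a number stays open as well, the 3' to 5' difference of GAPDH being 0.681 to 1.08 in number 3 and 0.412 to 0.574 in numbers 1 and 2. Solution incubation was compared with the KCl group at 3.5 h, so its calls, with the falls of PGD3, SIR and the reductant list, may hold a difference in nitrate, in RNA quality or between sets of arrays processed together. The array of whole roots in KCl at 2 h, replicate 2, has a nitrate index of 2.56, above the 3 nitrate arrays at 2 h, and whether its label is right stays open for nitrate at 2 h and for time.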

How the results depend on the processing

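The alternatives with array weights, array signal, a block on the compared arrays alone, or without the arrays that stand apart were chosen after seeing the data; the others were not. In the mean effect over the 5 populations, PGD3, HHO1, PGD1, HHO3 and PGM passed in each of its 39 alternatives and ATPC1 in 27, and its count stayed within 1.5 times in all but those named here or at that comparison. The counts for Peri and incubated roots depended on single arrays, and the cause was not tested except where array signal or arrays that stand apart are weighed for these counts. Arrays have no depth, and dim probe sets limit what can be seen: leaving them in took transitory nitrate in Peri from 13 to 3 calls, with more probe sets tested. Of 110 results that passed, each a named gene in 1 comparison, 13 no longer did without normalization of the sorted arrays, 24 with quantile normalization of the one-cycle arrays, 55 with only the compared arrays, 15 with array signal, 46 without the arrays that stand apart, 4 without the filter, 5 without the trend and 0 with the replicate block. On leaving out each array in turn, each pair of a gene result and a left-out array was counted, and 408 pairs were no longer past the threshold and 444 were. A gene in the mean over the 5 populations enters with 30 pairs, and one in any other comparison with 6. PGD3, HHO1, PGD1, HHO3, PGM, AT1G80380 and AT5G55050 passed in all of their 30, so the 444 overstate how the other results held. Of the 13 pathway lists fixed beforehand, only 3 had enough named members for camera, with 3 or 4 measured in each. Of their 32 calls 8 held with an estimated correlation, and of 87 for added lists 2 did. The 8 were the nitrate regulators in the mean over the populations, in continuous nitrate in EpiC, EndoP, Stele and protoplasts, and in transitory nitrate in EpiC, Stele and protoplasts. A pseudocount was not tried, since the values were already logged, and scan dates were empty and could not enter a model.

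With the replicate number as a block in the model of all arrays, counts were 6184 for solution incubation, 3 for transitory nitrate in Peri and 1 for nitrate under MSX, and the block moved none of the other 26 counts by over 1.5 times. With the block on the compared arrays alone, counts were 56 for continuous LRC and 1 for time, and it moved neither continuous EndoP nor whole roots at 3.5 h. In the comparisons where the numbers do not pair the arrays, they share only a number.

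Without normalization, counts were 1 for continuous LRC, 5919 for continuous Peri, 0 for transitory LRC, 21 for transitory EpiC, 2357 for transitory Peri, 3560 for the difference among populations, 41 for MSX without nitrate and 228 for glutamine. With quantile normalization, they were 1406 for continuous against transitory in incubated roots, 2 for digestion, 0 for solution incubation and 1 for time. Without the intensity trend 1 passed for transitory Stele. With only the arrays of the compared groups, counts were 1 for transitory incubated roots, 2418 for continuous against transitory in incubated roots, 1 for solution incubation, 1 for time, 7 for continuous EndoP, 3 for continuous Stele, 0 for transitory LRC, 27 for transitory EpiC, 2 for transitory Peri, 149 for the mean, 885 for the difference among populations, 14 for nitrate under MSX, 1 for MSX without nitrate and 26 for glutamine.

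Without the arrays that stand apart, which leaves 1 array each of incubated roots in KCl and in continuous nitrate, counts were 1 for continuous incubated roots, 0 for transitory incubated roots, 3 for continuous against transitory in incubated roots, 3 for digestion, 0 for solution incubation, 8 for continuous Stele, 518 for transitory Peri, 2 for the difference among populations, 1 for nitrate under MSX, 22 for MSX without nitrate and 323 for glutamine. With array signal as a covariate, they were 24 for digestion, 6616 for solution incubation, 8 for continuous Peri, 0 for transitory Peri, 68 for MSX without nitrate, 592 for glutamine and 3125 for the populations in KCl.

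Array weights did not converge and ranged from 0.0130 to 268, so their counts say little. They gave 928 for whole roots at 2 h, 11636 for continuous and 16712 for transitory incubated roots, 16711 between these, 221 for continuous protoplasts, 14833 for digestion, 16936 for solution incubation, 8396 for time, 2648 for continuous EpiC, 4690 for continuous EndoP, 13211 for continuous Peri, 12657 for continuous Stele, 39 for transitory LRC, 143 for transitory EndoP, 11758 for transitory Peri, 12039 for transitory Stele, 1190 for the mean, 16295 for the difference among populations, 67 for nitrate under MSX, 8595 for its change by MSX, 1203 for MSX without nitrate, 7842 for glutamine and 16939 for the populations. With weights and without the arrays that stand apart, they gave 3 for continuous and 3177 for transitory incubated roots, 15 for continuous protoplasts, 1845 for digestion, 2188 for solution incubation, 200 for time, 2731 for continuous EpiC, 4865 for continuous EndoP, 12969 for continuous Peri, 12702 for continuous Stele, 39 for transitory LRC, 27 for transitory EpiC, 46 for transitory EndoP, 11742 for transitory Peri, 12054 for transitory Stele, 409 for the mean, 15904 for the difference among populations, 68 for nitrate under MSX, 8525 for its change by MSX, 1225 for MSX without nitrate, 288 for glutamine and 16684 for the populations.

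On leaving out each array in turn, counts ranged from 0 to 13 for continuous protoplasts, 0 to 9974 for digestion, 0 to 2 for time, 0 to 11261 for transitory incubated roots, 0 to 11409 for solution incubation, 0 to 8317 for continuous against transitory in incubated roots, 0 to 2635 for continuous LRC, 0 to 44 for transitory LRC, 25 to 78 for continuous EpiC, 0 to 67 for transitory EpiC, 2 to 4390 for continuous Peri, 0 to 4181 for transitory Peri, 0 to 6 for continuous Stele, 0 to 80 for transitory Stele, 52 to 139 for the mean, 0 to 3523 for the difference among populations, 2 to 12 for MSX without nitrate and 15 to 238 for glutamine. Where this leaves a group with 1 or 2 arrays, they are assumed to vary like those of the other groups.

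Directions turned as follows. With array weights, LDH1 stood at -0.88 in whole roots at 2 h, CO2 at 0.47 in transitory incubated roots, -0.46 between continuous and transitory, -0.47 for solution incubation and 0.23 in continuous Stele, WES1 at 0.74 in continuous Peri, AED3 at -0.83 in transitory Peri and JKD at -0.53 in transitory Stele. With weights and without the arrays that stand apart, WES1 stood at 0.72 in continuous Peri, CO2 at 0.23 in continuous Stele, AED3 at -0.84 in transitory Peri and JKD at -0.54 in transitory Stele. Without the arrays that stand apart, camera turned direction for the autophagy list in whole roots at 2 h (adjusted p = 0.685) and for defence signalling in transitory EndoP (0.0364). It also turned for the autophagy list in continuous incubated roots (7.70e-07), digestion (0.0042) and solution incubation (0.305), the citrate cycle between continuous and transitory incubated roots (0.978), glutathione transferases in digestion (0.0481) and defence signalling in solution incubation (0.00373), where an incubated group then has 1 array and in continuous incubated roots both do, so these turns say little. With array signal, it turned for tubulins in transitory Stele (0.0132) and the citrate cycle under nitrate with MSX (0.0345).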

Other observations

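The genes and lists in the first paragraph were chosen after their values were seen; the splits of the arrays in the second were fixed beforehand.

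Glutamine under MSX and nitrate raised a group of loci beyond those already named: AT4G15700 by 3.46, AT4G15680 by 2.82, AT2G30540 by 2.32 and AT5G18600 by 1.84, besides AT4G15690. AT5G19120, which fell under MSX in KCl, rose by 2.93 with glutamine. Plastid-encoded genes moved as a group in several comparisons by camera at the preset correlation. Their median was 0.61 higher in continuous and 0.52 higher in transitory nitrate in protoplasts, -0.76 in continuous EpiC, 0.97 in transitory Stele and -1.13 between 3.5 h and 2 h in KCl, and none held with an estimated correlation (adjusted p = 0.722, 0.722, 0.722, 0.761 and 0.761). In the mean over the populations 3 of 10 genes of pentose phosphate and triose metabolism rose (0.023, adjusted p = 0.722 with an estimated correlation), PGD1, PGD3 and PGM. Of 41 glycosyltransferases 8 fell in continuous Peri (0.00202, adjusted p = 0.722 with an estimated correlation), where PYK10, a beta-glucosidase, fell by 2.07 (0.0366). PYK10 passed on leaving out 2 of the 6 arrays and in 6 of 15 alternatives, with adjusted p from 0.0294 to 0.659, and did not pass without KCl replicates 1 and 3 or nitrate replicates 2 and 3 (adjusted p up to 0.251).

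The arrays of each comparison were split anew into groups of the same sizes, the real split included. For the mean continuous effect over the 5 populations 3 of 100 splits gave as many calls as the 87 found, under the share of 0.05 set down beforehand. That share was not adjusted for the other comparisons, and the highest other split gave 1852 calls. The splits alone therefore do not exclude chance for the 87. For the populations in KCl only the real split of 100 reached 7922 calls, against at most 3453 in the others. Chance can be excluded there at 0.05, without adjustment for the other comparisons. The splits do not separate cell type from array signal, which in KCl was higher in EndoP and Stele than in the other populations. For the difference of the nitrate effect among populations, the change of the nitrate effect by MSX and continuous against transitory over the 5 populations, 0 calls were found, a count that any split reaches, so the splits do not test them; the highest others gave 2465, 4673 and 3594. Each remaining comparison has only 10 splits, too few for a share under 0.05. Of these, 1 of 10 reached the real count for transitory incubated roots (4964, highest other 0), continuous EpiC (94, 0), continuous Peri (3525, 3), transitory EpiC (58, 1), continuous against transitory in incubated roots (4098, 0), MSX without nitrate (13, 1), glutamine (134, 11) and solution incubation (3927, 0), 4 of 10 for transitory LRC (2, 27) and 3 of 10 for transitory Peri (13, 80). A real count of 0 is reached by any split: the highest other was 0 for whole roots at 2 h and 3.5 h, transitory EndoP, transitory Stele, continuous against transitory protoplasts, nitrate under MSX and time. It was 1 for continuous EndoP, 2 for continuous Stele and for transitory protoplasts, 4 for continuous protoplasts, 3847 for digestion, 3944 for continuous LRC and 8707 for continuous incubated roots. The split with 3944 calls set LRC in KCl, replicate 1, with nitrate replicates 1 and 3, and the one with 8707 set incubated roots in KCl, replicate 3, with nitrate replicates 1 and 3, leaving the 3 arrays with the lowest correlations on the other side. Where the replicate numbers pair the arrays (whole roots at 3.5 h, continuous LRC, continuous EndoP and time), the 4 splits that part as many pairs, the real one included, gave 0 calls; with the block 56 were found for continuous LRC, and the splits with more calls keep arrays of a number together. Such counts point to a structure of the arrays other than the treatment.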
